A study of Mus musculus with 24 samples.

How the data were processed

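Each library came with 7 tables of reads per reference sequence, for miRNA, tRNA, piRNA, rRNA, circRNA, lncRNA and a class named otherRNA. The values used here are counts as deposited by the authors: whole numbers in column 3 of tables laid out like the output of samtools idxstats. Per the submitters' processing notes, adapters were removed with cutadapt and reads were aligned with STAR 2.7.6a. Per the labels, the classes were searched in turn from miRNA through tRNA fragments, piRNA, rRNA and circRNA to lncRNA, and differences were tested with edgeR at a fold change of at least 1.5 and p under 0.01. The genome build, the annotation release, the counting strand, the handling of reads with several matches and whether that p was adjusted are not given in the sources used here. Because strand was not stated, reads on antisense genes are uncertain, and near-identical tRNA copies share reads in a way that is not stated either. The row that names no feature and the column of unmapped reads held 0 reads in every table.

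The libraries had 7.94 to 14.7 M reads over the 6 classes named in the mapping order. References numbered 3212 for miRNA (hairpin and mature entries together), 408 for tRNA, 85563 for piRNA, 358 for rRNA, 16444 for circRNA and 9500 for lncRNA. The otherRNA class is absent from the mapping order and was fitted apart. Transcript identifiers with their versions were matched to GENCODE M21 on GRCm38, which held 96.1% of lncRNA, 99.2% of rRNA and 98.0% of otherRNA identifiers. Coordinates of lncRNAs are those of this annotation. The circRNA tables carry coordinates of their own, and only 18.9% of them (2752 of 14538) lay inside the named host gene in GRCm38, so circRNAs are named without positions.

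The 6 classes were joined into a single matrix and fitted with edgeR 4.0.16 (quasi-likelihood test, two-sided) in R 4.3.3. Features were kept by filterByExpr on the group, which left 7454: 3564 circRNAs, 2070 piRNAs, 1208 lncRNAs, 340 tRNAs, 246 miRNA entries and 26 rRNAs. TMM factors ran from 0.626 to 1.31. The design had a term per group and a term for sequencing lane, 6 or 7 in the names of the sequencing runs. All 24 libraries shared the estimate of the spread, with a biological coefficient of variation of 34.6%. Values in CPM are counts scaled to TMM-adjusted library totals, RPM are reads scaled to the plain total of the 6 classes, and M after a depth stands for 1e6 reads. Log2 CPM values behind the correlations between libraries used a prior count of 2. Log2 fold changes of edgeR came from the fit with its default prior count. Adjusted p values are Benjamini-Hochberg values over the 7454 features, with a threshold of 0.05. The criterion named in the labels was applied to the same fit with unadjusted p. Limma 3.58.1 (voom with sample quality weights) and DESeq2 1.42.0 were run on the same matrix.

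Class shares and summed list reads were compared by exact two-sided permutation, with labels exchanged within lane. That gave 400 arrangements, and 0.005 was the smallest p they can give. Within a single lane of 3 against 3 libraries the smallest p was 0.1. Benjamini-Hochberg values covered the 18 share tests and, apart from those, the 120 tests of list sums. Intervals for differences in class shares and summed tRNA lists between exposed groups came from inverting the same permutation test at the 95% level. They were added after the first results had been seen. Of 200 simulated differences, 96.0% lay inside their permutation interval. Intervals for single features, including those against control and for the interaction, are 95% intervals from the edgeR log2 fold change and its SE. Permutations used numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15.

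The list tests covered 45 lists: 15 of miRNAs (let-7, miR-34 with miR-449, miR-200, miR-10 with miR-99, miR-100 and miR-125, miR-17 with miR-92, miR-29, miR-30, miR-27 with miR-130 and miR-301, paternal stress sperm miRNAs, the X-linked testis and Dlk1-Dio3 clusters, and erythrocyte, leukocyte, muscle and liver miRNAs), 22 tRNA families by amino acid, mitochondrial tRNA, tRNAs whose 5′ fragments are abundant in sperm, rRNA units, well-known lncRNAs, and mRNAs of sperm, epididymal epithelium, blood and smooth muscle. The 25 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, then with the correlation estimated, and with fry, in limma. Each list's members were also adjusted over the list alone.

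The features named were set by rule. Per comparison with control, class and direction, these were the 3 features with the smallest p at adjusted p under 0.05, or, with none, the 2 with the smallest p that met the criterion of the labels. The 3 most abundant features of each class and the 2 most abundant tested members of a list could also be named. These rules, the lists, the tests and most alternatives were chosen before the data were examined.

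The alternatives were DESeq2 size factors, library totals, each class scaled on its own, no filter, a filter of 10 CPM in 6 libraries, a robust spread, no lane term, a replicate block, tRNA summed per anticodon, otherRNA reads in the totals, only the 2 groups compared, each lane alone, and each library left out in turn. Shares were also computed with otherRNA reads in the total, without tRNA reads in the total, on the log2 scale, and with labels exchanged without regard to lane. Chosen after seeing the data were an extra term for libraries 5 and 6, the fits with libraries 1 to 4 or 5 and 6 alone, the list tests without control replicate 2, the summed list reads, the exchange of labels within libraries 5 and 6, the splits of the unfiltered fit, and the splits that balance lane and libraries 5 and 6.

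The fits were tested on simulated data drawn from negative binomial distributions with the estimated means, library sizes and spreads, with 200 of 7454 features changed in the DBP group in 10 simulations. At adjusted p under 0.05, edgeR called 5.52% of features changed 1.5-fold (37 of 670), 35.7% of those changed 2-fold (239 of 670) and 85.5% of those changed 4-fold (564 of 660). A mean of 2.3 unchanged features per simulation (at most 4) were called by edgeR. In 3 of these simulations DESeq2 called a mean of 10.7 (at most 17) and voom a mean of 3 (at most 4). In a simulated group with no change, edgeR called 0 features at adjusted p under 0.05, and a mean of 62.5 (50 to 73) met the criterion of the labels.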

Results

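Epididymosomes are vesicles shed into the epididymal lumen that carry RNA and protein to maturing sperm. Their RNA was sequenced from the cauda, the storage segment of the epididymis, in male C57BL/6J mice exposed to phthalates by osmotic pump over 6 weeks. DBP (dibutyl phthalate) and DEHP (di(2-ethylhexyl) phthalate) are phthalate diesters used as plasticisers. Control mice received the solvent, 50% DMSO, and other mice received 2.5 mg/kg/day of DBP, 2.5 mg/kg/day of DEHP, or both at 2.5 mg/kg/day each. Each of the 4 groups had 6 libraries, from 6 mice per the labels. Libraries 1 to 3 of every group were on lane 6 and libraries 4 to 6 on lane 7, so that lane and group were balanced.

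Reads on the 6 RNA classes came to 11.8, 12.8, 9.89, 12.8, 12.9 and 13.1 M in control libraries 1 to 6. In the DBP libraries they came to 10.6, 10.2, 9.84, 14.7, 10.8 and 10.99 M. The DEHP libraries held 10.5, 11.2, 11.002, 11.1, 11.9999 and 7.94 M, and the libraries of the mixture 11.4, 11.1, 10.2, 11.7, 12.1 and 9.49 M. Limits set by read number alone cover counting error only, while the SDs and SEs given are between libraries.

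The piRNA class held 48.9% of the reads of the 6 classes, the total for the class percentages that follow. Of piRNA reads, piR-mmu-30344366 alone took 20.7% ± 7.67 (SD, n = 24), piR-mmu-5890133 10.2% ± 5.43 and piR-mmu-398716 4.76% ± 1.27. Piwi-interacting RNAs are best known from germ cells, where they silence transposons. This class was searched before rRNA, circRNA and lncRNA, so reads that also match those classes would count as piRNA. Whether the reads of this class come from true piRNAs was not tested. The tRNA class held 35.7% of reads. The arginine tRNA tRNA-Arg-CCG-3-1 took 38.0% ± 5.58 of tRNA reads, tRNA-Pro-TGG-1-1 5.24% ± 1.46 and tRNA-Arg-TCG-1-1 2.15% ± 0.712. Reads on rRNA were 4.57% of the total, of which the transcript ENSMUST00000198477.2 took 97.0% ± 2.52 and the mitochondrial mt-Rnr2 and mt-Rnr1 1.66% ± 1.60 and 0.567% ± 0.702. The circRNA class held 4.39%, led by mmu_circ_0000691 (host gene 2610528E23Rik, 11.5% ± 3.59 of circRNA reads), mmu_circ_0013891 (Maz, 8.97% ± 6.21) and mmu_circ_0000336 (7.56% ± 2.14). The counts do not show which reads crossed the junction that closes the circle. Here and below, circRNA reads can therefore not be told apart from reads of the linear host RNA. The lncRNA class held 0.796%, led by AC121821.1 (ENSMUST00000235679.1, chromosome 18, 35553371 to 35558316 in GRCm38) with 24.7% ± 12.1 of lncRNA reads.

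The miRNA class held 5.66% of reads, and only 12.2% of these lay on entries of mature miRNAs. Whether a read counted on a hairpin was also counted on its mature entry is not given in the sources used here, and mmu-mir-2137 alone had 1156858 reads on the hairpin and 1143908 on mature entries. The hairpins mmu-mir-1961, mmu-mir-1928 and mmu-mir-3535 took 12.4% ± 4.87, 11.1% ± 3.11 and 10.9% ± 2.83 of the class (SD, n = 24). Families known from sperm and epididymis had few reads: let-7, a repressor of growth genes, had 8.23 ± 2.005 RPM (SD, n = 24), with 51 to 156 reads per library on the mature entries of the list. Over all let-7 entries 2457 reads were mature and 4772 lay on hairpins. The group of miR-10, miR-99, miR-100 and miR-125 had 2.24 ± 1.03 RPM, miR-17 and miR-92 2.50 ± 1.32, miR-29 0.969 ± 0.456, miR-200 0.693 ± 0.422, miR-30 0.485 ± 0.296, miR-34 and miR-449 0.458 ± 0.328 and miR-27, miR-130 and miR-301 0.347 ± 0.320. The X-linked testis cluster had 0.724 ± 0.414 RPM, the Dlk1-Dio3 cluster 0.379 ± 0.184 and the sperm miRNAs linked to paternal stress 0.442 ± 0.282. Among miRNAs of other tissues, muscle miRNAs had 16.1 ± 8.90 RPM, mostly miR-145a-5p (3047 reads over 24 libraries) and miR-143-3p (1360 reads). Leukocyte miRNAs had 0.579 ± 0.362, erythrocyte miRNAs 0.0896 ± 0.119 and the liver miRNA miR-122-5p 0.0818 ± 0.106 RPM. The lists of sperm, epididymal, blood and smooth muscle mRNAs were searched by gene symbol in the lncRNA and otherRNA classes only, and matched 0 features. No mRNA table was among those given, so this does not show whether such mRNAs were present. The mitochondrial tRNA list matched 0 features of the tRNA class. In the otherRNA class lay 22 mitochondrial tRNA sequences, 10 of them with enough reads to be tested there.

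Whether exposure altered the make-up of the vesicle RNA was asked with the class shares. The tRNA share was 33.7% ± 5.64 (SD, n = 6) in controls, 36.0% ± 5.47 after DBP, 37.5% ± 3.80 after DEHP and 35.8% ± 6.06 after the mixture. The piRNA share was 49.9% ± 4.85, 49.1% ± 3.96, 47.4% ± 3.07 and 49.0% ± 4.98 in the same order. The rRNA share was 5.10% ± 0.672 in controls against 4.39% ± 0.950, 4.30% ± 0.353 and 4.55% ± 0.709, and 1, 0 and 1 of 6 exposed libraries lay above the control mean. Shares of miRNA (5.84% ± 0.702, 5.55% ± 1.08, 5.67% ± 0.335 and 5.51% ± 0.654), circRNA (4.64% ± 0.734, 4.22% ± 1.04, 4.30% ± 0.676 and 4.42% ± 0.763) and lncRNA (0.847% ± 0.171, 0.768% ± 0.0632, 0.823% ± 0.124 and 0.755% ± 0.0756) are given in the same order, and none differed from control at an unadjusted p under 0.05 by exact permutation. The exact permutation p for rRNA was 0.05 for DBP, 0.045 for DEHP and 0.195 for the mixture (n = 6), and none passed the adjustment over 18 tests (0.45, 0.45 and 0.732). The tRNA differences of 2.36, 3.83 and 2.13 percentage points had exact permutation p of 0.48, 0.205 and 0.53 (n = 6). With 1 library left out the tRNA difference ranged from 0.805 (without DBP replicate 1) to 4.06 (without control replicate 4) for DBP, from 2.77 (without control replicate 6) to 5.54 (without control replicate 4) for DEHP, and from 0.708 (without mixture replicate 1) to 3.83 (without control replicate 4) for the mixture. The piRNA difference turned from below 0 to 0.237 for DBP and 0.161 for the mixture without control replicate 6, and also lay above 0 without control replicate 2 or without replicate 1 of the exposed group. By lane, rRNA differed by -0.436 (lane 6) and -0.999 (lane 7) percentage points for DBP, -1.42 and -0.188 for DEHP, and -0.878 and -0.230 for the mixture. The tRNA share was 5.88, 6.14 and 6.11 percentage points higher on lane 6, but differed by -1.16, 1.53 and -1.85 on lane 7, where a permutation p can reach only 0.1.

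**Figure D1:**
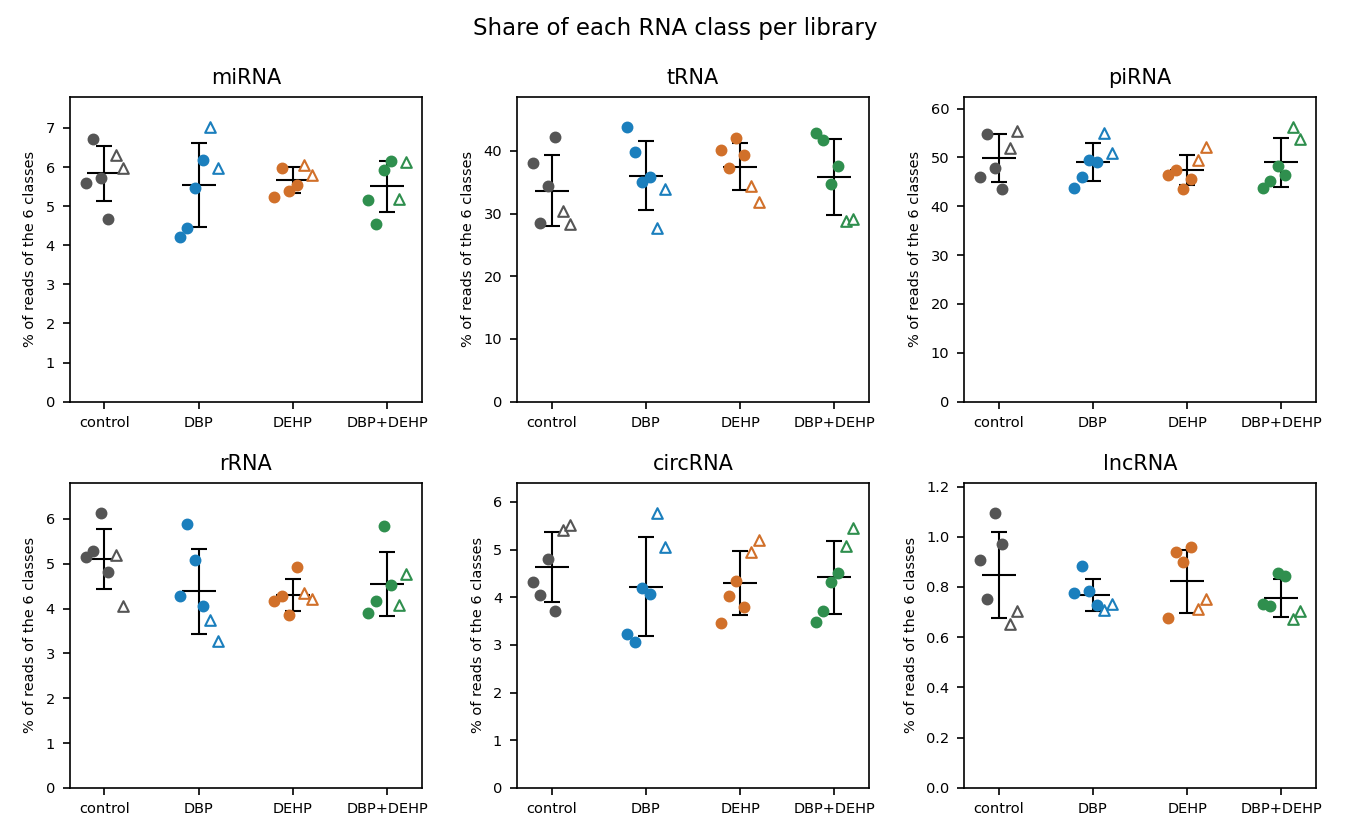
Percent of the reads of the 6 classes that fell on each class, a panel per class, by group; circles are libraries 1 to 4, triangles libraries 5 and 6, and bars the mean ± SD (n = 6). The tRNA share averaged 33.7% in controls and 36.0%, 37.5% and 35.8% in the exposed groups, and 30.6% in the 8 libraries numbered 5 and 6 against 38.3% in the other 16.

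Libraries 5 and 6 of each group shared a profile. The methionine tRNA tRNA-Met-CAT-2-1 stood at 192 ± 27.8 CPM in these 8 libraries and at 981 ± 104 in the other 16 (SD), and tRNA-Met-CAT-1-1 at 831 ± 181 against 4528 ± 1011. The piRNA piR-mmu-4000196 had 4808 ± 448 CPM against 1172 ± 111, and piR-mmu-71530 9440 ± 3295 against 933 ± 206. On the first principal component all 4 libraries numbered 4, sequenced on the same lane, lay nearer to libraries 1 to 3, while control replicate 2, at 12.6, lay nearer to libraries 5 and 6. The tRNA share of libraries 5 and 6 was 30.6% ± 2.59 (SD, n = 8) against 38.3% ± 4.01 (SD, n = 16), and their piRNA share 53.2% ± 2.38 against 46.7% ± 2.88. A term for these libraries, fitted beside lane with edgeR, called 1167 features at adjusted p under 0.05 (635 higher, 532 lower), and the lane term beside it called 3. Without that term the lane term called 923. The term for libraries 5 and 6 was chosen after the profile was seen in the same counts, so its calls describe the profile and do not test it. The tRNAs and piRNAs named above were taken from the features with the smallest p of that term. The labels name no batch that sets libraries 5 and 6 apart.

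**Figure D2:**
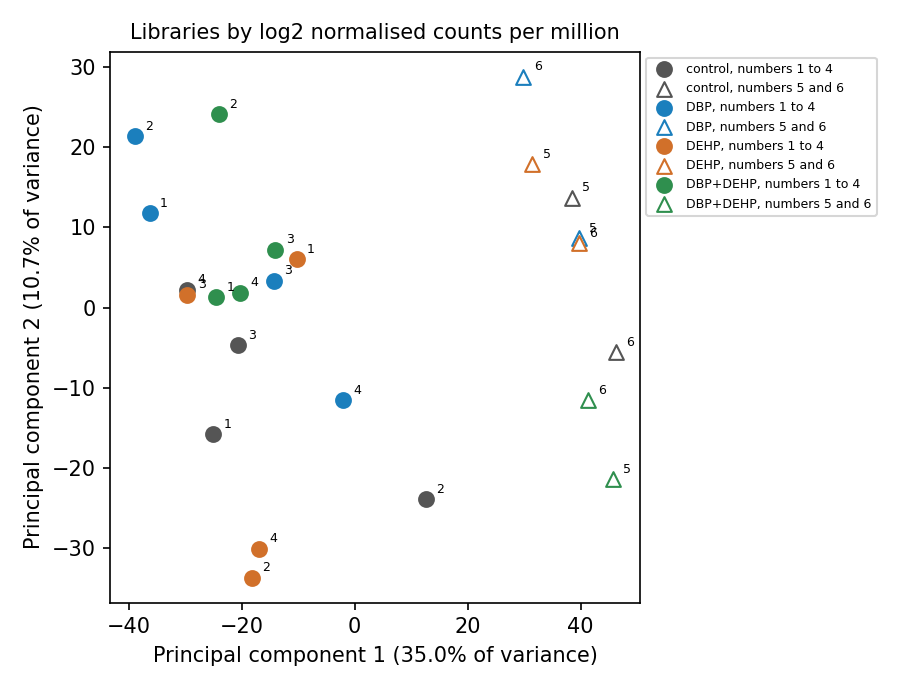
First and second principal components of log2 CPM over the tested features, with 35.01% and 10.7% of the variance, by group and library number. Libraries 5 and 6 of every group averaged 39.1 on the first component and libraries 1 to 3 averaged -20.3.

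The comparison of DBP with control asked which vesicle RNAs differed after DBP alone. The tyrosine tRNAs tRNA-Tyr-GTA-1-1 and tRNA-Tyr-GTA-1-5 had log2 fold changes of 0.92 ± 0.25 and 0.97 ± 0.29 (SE, n = 6), at 5.34 ± 2.66 CPM (SD) against 2.702 ± 0.842 and 3.93 ± 1.45 against 1.94 ± 0.734, with 6 of 6 exposed libraries above the control mean. The piRNA piR-mmu-10824347 was at 13.2 ± 8.18 CPM against 5.65 ± 2.82 (log2 1.23 ± 0.38), and piR-mmu-6254633 at 1.04 ± 0.232 against 2.57 ± 1.24 (-1.33 ± 0.36). The circRNA mmu_circ_0006732, from the beta-tubulin gene Tubb5, was at 3.74 ± 0.683 CPM against 2.34 ± 0.595 (0.69 ± 0.20). None of these passed the adjustment in edgeR (adjusted p = 0.934 each), so they met only the criterion of a 1.5-fold difference at p under 0.01. So did piR-mmu-10967865 (1.17), piR-mmu-8080339 (-1.08), mmu_circ_0012943 (Gm15492, 0.62), mmu_circ_0000713 (-0.99) and mmu_circ_0013704 (Rnf169, -1.45). The lincRNAs Gm12031 (chromosome 11, 20145567 to 20146344, log2 0.74), Gm40915 (chromosome 13, 37616964 to 37627571, -1.05) and Gm6116 (chromosome 5, 74949190 to 74966368, -1.25) did so too. By lane, tRNA-Tyr-GTA-1-1 had log2 fold changes of 1.50 (lane 6) and 0.32 (lane 7), piR-mmu-10824347 1.81 and 0.78, piR-mmu-6254633 -1.55 and -1.11, and mmu_circ_0006732 0.62 and 0.70. Of the 13 named features, the 11 with a value on both lanes had the same sign on each. They were chosen by p in the fit of both lanes, which favours the same sign, so this is no separate support. The criterion was met whichever single library was left out by 6 of the 13, among them tRNA-Tyr-GTA-1-1, piR-mmu-6254633 and mmu_circ_0006732, and not by tRNA-Tyr-GTA-1-5 (without control replicate 1 or 2 or DBP replicate 2) or piR-mmu-10824347 (without control replicate 1 or 2 or DBP replicate 6).

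At adjusted p under 0.05, edgeR called 0 of 7454 features for DBP, DESeq2 0 and voom 0. At unadjusted p under 0.05 edgeR called 366, where chance gives 372.7, DESeq2 390 and voom 530. For tRNA edgeR called 57 of 340, where chance gives 17 on average, against 9 for DEHP and 11 for the mixture. Features of a tRNA list moved together (median estimated correlation 0.678 in the called lists), so the number can lie far from 17 by chance. The criterion of the labels was met by 54 features (28 higher, 26 lower): 31 piRNAs, 13 circRNAs, 7 tRNAs, all higher, and 3 lncRNAs, with 0 miRNA entries and 0 rRNAs. DESeq2 gave 66. With each class scaled on its own 29 were higher and 17 lower. The number was 24 without control replicate 2, 165 without control replicate 4 and 111 without DBP replicate 4. With no filter on low counts, edgeR called 71 features at adjusted p under 0.05 (5 higher), 58 of them piRNAs. Of these 71, 68 pass the filter and 0 had under 10 reads in all, with a median of 2167 reads. Among them were piR-mmu-10824347 (adjusted p = 0.0177 in edgeR), piR-mmu-6254633 (0.0124) and mmu_circ_0013704 (0.0395). Of 25 splits of the same libraries fitted without a filter, the real one included, 4 called at least 71. The others had a median of 17.5 and a highest of 441, so chance could not be excluded for these calls. The abundant piR-mmu-30344366 had a log2 difference of 0.54 (95% interval -0.25 to 1.32), piR-mmu-5890133 -0.70 (-1.63 to 0.23) and tRNA-Arg-CCG-3-1 0.01 (-0.73 to 0.76).

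Histidine tRNAs had the highest median log2 difference of the tRNA families after DBP on the joint scaling, without passing a test over all features. Their summed reads were 22985 ± 8941 RPM (SD, n = 6) against 13732 ± 5621, with 5 of 6 exposed libraries above the control mean (exact permutation p = 0.09, adjusted 0.467). All 10 tested tRNA-His features were higher, with a median log2 difference of 0.83, and 9 passed at adjusted p under 0.05 when adjusted over the list alone (smallest 0.0373), against 0 when adjusted over all features. The median was 1.73 on lane 6 and -0.04 on lane 7. All 9 tRNA-Tyr features were higher (median 0.62, lane 6 1.08, lane 7 0.28), and 7 passed when adjusted over the list alone (smallest 0.0118), against 0 over all features. Summed tRNA-Tyr reads were 145 ± 36.0 RPM against 101 ± 41.1 (6 of 6 above the control mean, n = 6, exact permutation p = 0.06, adjusted 0.467). In the 23 other tested lists 0 members passed when adjusted over the list alone. That adjustment does not cover the number of lists or comparisons. Near-identical tRNA copies share reads in a way that is not stated. Counts of features within a tRNA family, here and below, are therefore not separate confirmations. Of 25 lists, camera at the preset correlation called 17 higher than other features, led by tRNA-Tyr (adjusted p = 8.61e-12), tRNA-His (5.30e-11) and tRNA-Ile (8.62e-10). With an estimated correlation 0 of them held, and the smallest adjusted p = 0.223 with an estimated correlation was shared by tRNA-Tyr, tRNA-His, tRNA-Ile and tRNA-Thr. The smallest adjusted p of fry was 0.175.

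The other lists called after DBP were tRNA-Leu (adjusted p = 2.48e-09), the tRNAs of sperm 5′ fragments (2.48e-09), tRNA-Ala and tRNA-Thr (1.64e-08 each), tRNA-Arg (1.14e-06), and tRNA-Gly, tRNA-Trp, tRNA-Ser, tRNA-Gln, tRNA-Asn, tRNA-Lys, tRNA-Phe, tRNA-Pro and tRNA-iMet, the last at 0.00840. Of these calls 0 were left with the correlation estimated, where the smallest of any list was adjusted p = 0.223 with an estimated correlation. Not called were tRNA-Glu (0.140), well-known lncRNAs such as Malat1 and Neat1 (0.208), rRNA units (0.391), tRNA-Met (0.410), tRNA-Val (0.740), tRNA-Asp (0.835), tRNA-Cys (0.865) and let-7 (0.954). The rRNA units, matched by gene symbol, leave out ENSMUST00000198477.2 in every comparison. That transcript held 97.0% ± 2.52 (SD) of rRNA reads, so the list does not test the rRNA share. For tRNA-Cys and let-7 the median log2 difference was above 0 (0.01 and 0.10) while the test pointed lower. Malat1 differed by 0.06 ± 0.16 (SE) and Neat1 by 0.01 ± 0.26. Medians of all 21 tRNA families lay above 0 on the joint scaling, but 18 did with library totals. With each class scaled on its own, which centres the class near 0 by construction (tRNA median 0.04), 13 did, and that of the tRNAs of sperm 5′ fragments (0.23 on the joint scaling, lane 6 0.45, lane 7 -0.03) became -0.05. On lane 6 20 of 21 lay above 0, and on lane 7 it was 7. Sperm miRNAs linked to paternal stress summed to 0.194 ± 0.175 RPM against 0.529 ± 0.292 in controls, with 0 of 6 above the control mean (n = 6, exact permutation p = 0.04, adjusted 0.467). The liver miRNA miR-122-5p was at 0.113 ± 0.0761 RPM against 0.0426 ± 0.0475, with 5 of 6 above it (n = 6, exact permutation p = 0.045, adjusted 0.467). Both contrasts rest on very few reads. The paternal stress list had 120 reads over 24 libraries (0 to 14 per library) and miR-122-5p had 21 (0 to 5 per library).

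**Figure D3:**
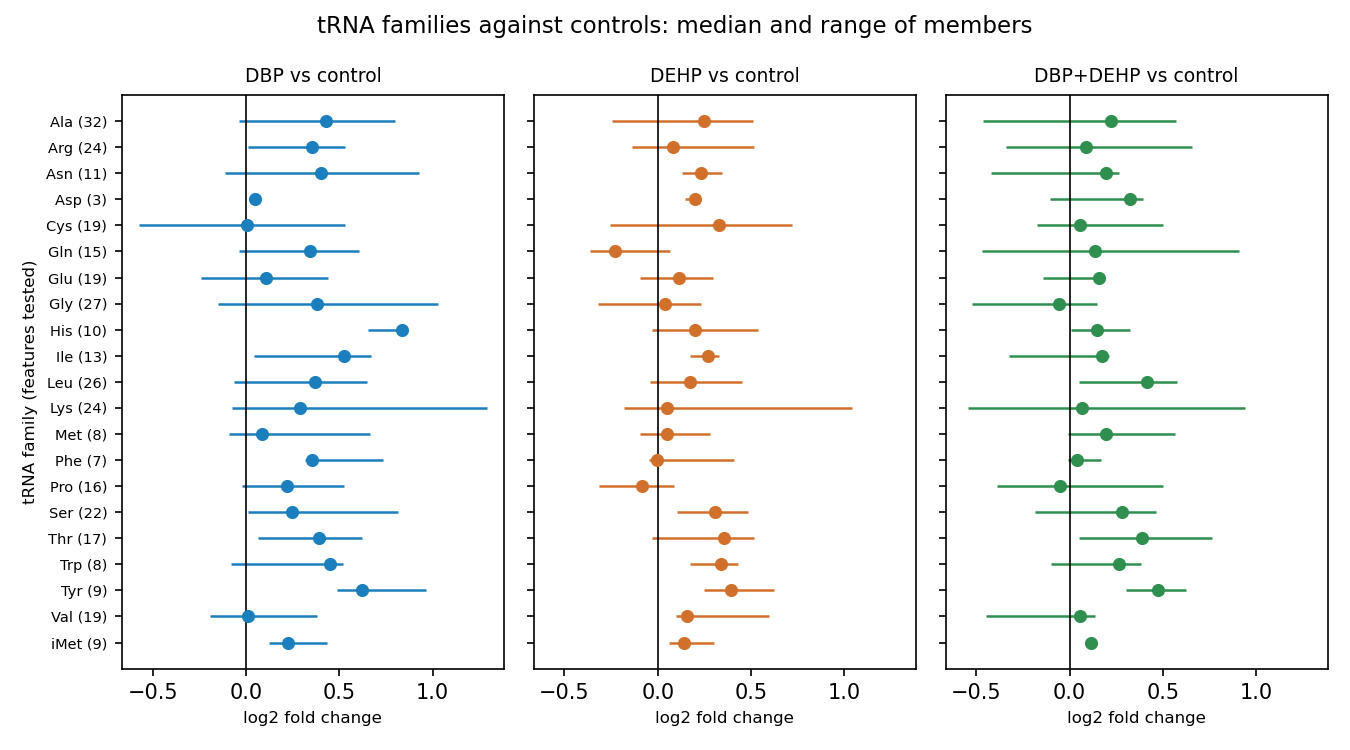
Log2 difference from control of tRNA features by family on the joint scaling, a panel per exposure; dots are medians over the tested features of a family and lines their range. After DBP tRNA-His had the highest median (0.83, and -0.04 on lane 7 alone), and the number of 21 families above 0 was 21, 18 and 19 in the panels, and 13, 9 and 7 with each class scaled on its own, which centres the tRNA class near 0 by construction.

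The comparison of DEHP with control asked the same of DEHP alone. The piRNA piR-mmu-23561793 stood at 13.8 ± 2.95 CPM (SD, n = 6) against 7.19 ± 2.55 (log2 0.94 ± 0.29, SE), with 6 of 6 exposed libraries above the control mean, and piR-mmu-2004057 at 4.18 ± 1.16 against 6.26 ± 0.902 (-0.59 ± 0.19), with 0 of 6. The circRNA mmu_circ_0013375 of Dennd2a, a gene for a Rab exchange factor, was at 1.23 ± 0.273 CPM against 0.551 ± 0.249 (1.15 ± 0.28), and mmu_circ_0003443 of Zfp207 at 1.49 ± 0.214 against 2.38 ± 0.522 (-0.67 ± 0.18). The lincRNA 4930570E03Rik (chromosome 16, 78695034 to 78709083) was at 1.23 ± 0.306 CPM against 0.571 ± 0.284 (1.09 ± 0.33). None passed the adjustment in edgeR (adjusted p = 0.999 each), and all 5 met only the criterion of the labels. The others that did were piR-mmu-73346 (0.99), piR-mmu-6644755 (-1.20), mmu_circ_0001559 (Zfp536, 0.88), mmu_circ_0008089 (Clasp1, -0.75), and the lincRNAs Gm15907 (chromosome 13, 94137447 to 94140117, log2 0.75), 4930556L07Rik (chromosome 2, 151747578 to 151749978, -0.87) and Gm1627 (chromosome 1, 133962162 to 133971938, -0.94). On lanes 6 and 7 piR-mmu-23561793 had log2 fold changes of 0.96 and 0.90, mmu_circ_0013375 1.14 and 1.14, and mmu_circ_0003443 -0.72 and -0.65. The criterion was met whichever library was left out by 4 of the 12 named features, among them piR-mmu-23561793, mmu_circ_0013375 and 4930570E03Rik, and not by mmu_circ_0003443 (without control replicate 2) or piR-mmu-2004057 (without any of 7 libraries).

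For DEHP edgeR called 0 features at adjusted p under 0.05, DESeq2 0 and voom 0, with 218, 203 and 323 at unadjusted p under 0.05, where chance gives 372.7. The criterion of the labels was met by 29 features (14 higher, 15 lower), of which 15 were circRNAs, 8 piRNAs and 6 lncRNAs, with 0 tRNAs, miRNA entries or rRNAs. With library totals 14 were higher and 5 lower, and with each class scaled on its own 12 and 8. Without control replicate 4 the number was 62. With no filter on low counts 6 piRNAs were called at adjusted p under 0.05. Threonine tRNAs had the smallest p of camera at the preset correlation (adjusted p = 2.07e-07), which was lost with an estimated correlation (adjusted p = 0.560 with an estimated correlation). In this family 16 of 17 tRNA-Thr features were higher (median 0.36, lane 6 0.52, lane 7 0.18), and their summed reads were 4957 ± 930 RPM (SD, n = 6) against 3813 ± 684 (exact permutation p = 0.045, adjusted 0.467). The tRNAs of sperm 5′ fragments summed to 115703 ± 9067 RPM against 102899 ± 7862, with 6 of 6 above the control mean (n = 6, exact permutation p = 0.035, adjusted 0.467), and their median of 0.12 (lane 6 0.16, lane 7 -0.00) became -0.11 with each class scaled on its own, which centres the tRNA class near 0 (-0.06) by construction. All 4 tested let-7 members were higher (median 0.41), with summed reads of 9.95 ± 1.96 RPM against 7.98 ± 1.70 (n = 6, exact permutation p = 0.04, adjusted 0.467).

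For DEHP camera at the preset correlation called 14 lists, all higher: tRNA-Thr (adjusted p = 2.07e-07), tRNA-Ser (9.63e-06), tRNA-Tyr, tRNA-Trp, tRNA-Leu, tRNA-Cys, tRNA-Ile, tRNA-Ala, the tRNAs of sperm 5′ fragments, tRNA-Asn, tRNA-Val, tRNA-His, tRNA-Arg (0.0134) and let-7 (0.0240). With an estimated correlation 0 held (smallest adjusted p = 0.560 with an estimated correlation, let-7 included), and 0 members of any list passed when adjusted over the list alone or over all features. The smallest adjusted p of fry was 0.753. Not called were tRNA-Glu (0.0694), tRNA-iMet, tRNA-Asp and tRNA-Lys (0.121 each), tRNA-Gln (0.157, lower), tRNA-Gly and tRNA-Met (0.364 each), tRNA-Phe (0.383), well-known lncRNAs (0.693), tRNA-Pro (0.711, lower) and rRNA units (0.871, lower). For tRNA-Phe and the lncRNAs the median was below 0 (-0.01 and -0.08) while the test pointed higher. Medians of 18 of 21 tRNA families lay above 0, against 20 with library totals and 9 with each class scaled on its own and so centred near 0, where tRNA-Leu (0.17) and tRNA-Arg (0.08) became -0.10 each. By lane 21 lay above 0 on lane 6 and 12 on lane 7.

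The comparison of the mixture with control asked what combined exposure did. The threonine tRNA tRNA-Thr-CGT-1-1 was at 64.2 ± 27.3 CPM (SD, n = 6) against 36.5 ± 11.5 (log2 0.76 ± 0.25, SE), with 4 of 6 exposed libraries above the control mean. The circRNA mmu_circ_0001559 of Zfp536, a zinc-finger gene, was at 1.48 ± 0.391 CPM against 0.692 ± 0.239 (1.10 ± 0.26), and mmu_circ_0015327 of Arpp21 at 1.05 ± 0.309 against 0.372 ± 0.0921 (1.45 ± 0.40). The piRNA piR-mmu-8235014 was at 1.54 ± 0.287 CPM against 2.68 ± 0.779 (-0.79 ± 0.19), with 0 of 6 libraries above the control mean. The lincRNA Gm10646 (ENSMUST00000213227.1, chromosome 9, 67102300 to 67109601) had a log2 fold change of 3.06, but it rested on mixture replicate 6 with 89.2 CPM, while the other 5 libraries of the mixture had 1.21 to 1.74 CPM, and without that library it was 0.12. None passed the adjustment in edgeR (adjusted p = 1.00 each), and these met only the criterion of the labels, as did piR-mmu-61040 (0.66), piR-mmu-49703152 (1.25), piR-mmu-631298 (-0.74), mmu_circ_0006649 (Taf11, -1.05), Gm49497 (chromosome 15, 61184151 to 61241065, log2 -0.94) and AC118695.1 (chromosome 19, 56035096 to 56040941, -0.85). On lanes 6 and 7 tRNA-Thr-CGT-1-1 had log2 fold changes of 1.07 and 0.40, mmu_circ_0001559 0.63 and 1.55, mmu_circ_0015327 1.72 and 1.25, piR-mmu-8235014 -0.95 and -0.64, and Gm10646 0.08 and 4.47. Of the 12 features taken by the naming rule, 11 of which are given here, 6 met the criterion whichever library was left out, among them mmu_circ_0001559, mmu_circ_0015327 and piR-mmu-8235014, and tRNA-Thr-CGT-1-1 did not without any of 5 libraries.

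For the mixture edgeR called 0 features at adjusted p under 0.05, DESeq2 0 and voom 0, with 203, 179 and 320 at unadjusted p under 0.05, where chance gives 372.7. The criterion of the labels was met by 31 features (14 higher, 17 lower): 16 circRNAs, 11 piRNAs, 3 lncRNAs and 1 tRNA, with 0 miRNA entries and 0 rRNAs. With library totals 13 were higher and 10 lower. The number was 58 without control replicate 4 and 50 without mixture replicate 5. With no filter on low counts 5 features were called at adjusted p under 0.05, Gm10646 among them (adjusted p = 3.06e-19 in edgeR). Leucine tRNAs had the smallest p of camera at the preset correlation (adjusted p = 2.55e-14), which was lost with an estimated correlation (adjusted p = 0.285 with an estimated correlation). All 26 tRNA-Leu features were higher (median 0.42, lane 6 0.57, lane 7 -0.05), with summed reads of 5331 ± 947 RPM (SD, n = 6) against 3919 ± 793 and 5 of 6 libraries above the control mean (exact permutation p = 0.04, adjusted 0.467). All 17 tRNA-Thr features were higher as well (median 0.39, lane 6 0.56, lane 7 0.13). Summed tRNAs of sperm 5′ fragments were 111954 ± 19670 RPM against 102899 ± 7862.

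After the mixture camera at the preset correlation called 13 lists, all higher: tRNA-Leu (adjusted p = 2.55e-14), tRNA-Thr (1.08e-08), tRNA-Tyr (3.52e-08), tRNA-Ser (1.56e-06), tRNA-Ala, tRNA-Trp, tRNA-Arg, the tRNAs of sperm 5′ fragments (0.00839), tRNA-Asn, tRNA-Glu, tRNA-His, tRNA-Cys (0.0407) and tRNA-Ile (0.0426). With an estimated correlation 0 held (smallest adjusted p = 0.285 with an estimated correlation), and 0 members of any list passed when adjusted over the list alone or over all features. The smallest adjusted p of fry was 0.480. Without control replicate 2 camera called 6 lists for the mixture, 18 for DBP and 12 for DEHP (11 of them higher). Not called for the mixture were tRNA-Asp (0.0625), tRNA-iMet and tRNA-Lys (0.0683 each), tRNA-Gln (0.0861), tRNA-Met (0.113), tRNA-Pro (0.190), rRNA units (0.266, lower), tRNA-Phe and let-7 (0.289 each, let-7 lower), tRNA-Val (0.411), well-known lncRNAs (0.744) and tRNA-Gly (0.895, lower). For tRNA-Pro and the lncRNAs the median was below 0 (-0.05 and -0.13) while the test pointed higher. Medians of 19 of 21 tRNA families lay above 0, against 20 with library totals and 7 with each class scaled on its own and so centred near 0, where tRNA-His (0.14) and tRNA-Ile (0.18) became -0.01 and -0.02 and the tRNAs of sperm 5′ fragments (0.10, lane 6 0.30, lane 7 -0.16) became -0.12. By lane 20 lay above 0 on lane 6 and 6 on lane 7. The selenocysteine tRNA, a family of 1 member, had exact permutation p of 0.745, 0.375 and 0.995 for DBP, DEHP and the mixture (n = 6).

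The comparison of DBP with DEHP asked whether the diesters differed at the same dose by weight. Histidine tRNAs summed to 22985 ± 8941 RPM (SD, n = 6) after DBP and 17215 ± 5227 after DEHP, a log2 difference of 0.37 (95% interval -0.29 to 1.12). The valine tRNAs summed to 24089 ± 5105 and 31751 ± 10159 RPM (-0.37, -0.92 to 0.08), and the cysteine tRNAs to 4191 ± 1369 and 5664 ± 1350 (-0.45, -0.94 to 0.15). For tRNA-Tyr the difference was 0.21 (-0.45 to 1.03), for tRNA-Thr -0.10 (-0.48 to 0.28), and for the tRNAs of sperm 5′ fragments -0.05 (-0.21 to 0.13). Among abundant features, piR-mmu-30344366 differed by 0.58 (-0.20 to 1.36), piR-mmu-5890133 by -0.75 (-1.68 to 0.18), tRNA-Arg-CCG-3-1 by -0.01 (-0.74 to 0.73), mmu-mir-1961 by -0.00 (-0.59 to 0.59) and mt-Rnr2 by -0.58 (-1.83 to 0.68). The tRNA share differed by -1.47 percentage points (-6.31 to 3.28), piRNA by 1.63 (-2.09 to 5.64) and rRNA by 0.0850 (-0.828 to 0.981). These intervals leave room for differences in either direction. At adjusted p under 0.05 edgeR called 0 features, DESeq2 0 and voom 0, with 263, 250 and 286 at unadjusted p under 0.05 and 28 at the criterion of the labels (14 higher, 14 lower). With no filter on low counts edgeR called 3 features, 2 of which pass the filter. Of 69 exact permutation tests of tRNA lists between exposed groups 0 had p under 0.05, and the 18 of class shares had adjusted p of 0.98 each. The feature with the smallest p, named after its values were seen, was mmu_circ_0004600 of Ranbp9, with a log2 difference of -1.41 ± 0.32 (SE, edgeR adjusted p = 1.00).

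The mixture was compared with each diester to ask what the added compound did. Against DBP alone, histidine tRNAs summed to 15256 ± 2796 against 22985 ± 8941 RPM (SD, n = 6), a log2 difference of -0.51 (95% interval -1.16 to 0.14), with 0 of 6 mixture libraries above the mean of the other group. Aspartate tRNAs differed by 0.33 (-0.02 to 0.68) and piR-mmu-30344366 by -0.55 (-1.33 to 0.23). Against DEHP alone, threonine tRNAs differed by -0.17 (-0.44 to 0.15) and leucine tRNAs by 0.19 (-0.21 to 0.58). Against DBP, edgeR called 0 features at adjusted p under 0.05, DESeq2 0 and voom 0, with 284, 263 and 356 at unadjusted p under 0.05 and 47 at the criterion of the labels (25 higher, 22 lower). Against DEHP the calls were again 0 by each tool, with 222, 184 and 279 at unadjusted p under 0.05 and 41 at the criterion (17 higher, 24 lower). With no filter on low counts 17 features were called against DBP and 3 against DEHP. The features with the smallest p, named after their values were seen, were the lncRNA Gm49007 against DBP (0.93 ± 0.23, SE, edgeR adjusted p = 1.00) and mmu_circ_0004600 of Ranbp9 against DEHP (-1.41 ± 0.32, edgeR adjusted p = 0.791).

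A test of interaction asked whether the mixture departed from the sum of the log2 effects of its parts. The circRNA mmu_circ_0013375 of Dennd2a, named after its values were seen, had the smallest p: its log2 difference from control was 0.78 ± 0.29 (SE, n = 6) after DBP, 1.15 ± 0.28 after DEHP and -0.12 ± 0.32 after the mixture. Its departure from the sum was -2.06 ± 0.41, which did not pass the adjustment (edgeR adjusted p = 0.345). For piR-mmu-30344366 the departure was -0.50 (95% interval -1.60 to 0.59) and for tRNA-Arg-CCG-3-1 -0.07 (-1.11 to 0.98). At adjusted p under 0.05 edgeR called 0 features, DESeq2 0 and voom 0. At unadjusted p under 0.05 edgeR called 4.04% of the 7454 features, DESeq2 284 features and voom 467. With no filter on low counts edgeR called 20 features at adjusted p under 0.05.

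The 3 comparisons with control shared the same control libraries, which makes their fold changes correlate by construction. Features at the criterion in the same direction numbered 4 for DBP and DEHP (piR-mmu-73346, piR-mmu-8080339, piR-mmu-23561793 and mmu_circ_0012943 of Gm15492), 3 for DBP and the mixture (piR-mmu-49703152, mmu_circ_0003188 of Epn2 and mmu_circ_0004600 of Ranbp9) and 3 for DEHP and the mixture (piR-mmu-631298, piR-mmu-6644755 and mmu_circ_0001559 of Zfp536). Simulations with no shared effect but shared controls gave means of 8.45, 8.15 and 7.85 such features. The overlap depends on how many features meet the criterion. That number was 54 for DBP, 29 for DEHP and 31 for the mixture, against a mean of 62.5 in a simulated group with no change. The real and simulated overlaps are therefore not directly comparable, and no conclusion on sharing is drawn from them. Across 7454 features, which are not independent replicates, r between log2 fold changes was 0.55, 0.48 and 0.50. In the 20 simulations with shared controls its means were 0.50, 0.49 and 0.50 (0.478 to 0.525, 0.463 to 0.511 and 0.468 to 0.522). For DBP and DEHP r lay above the highest simulated, but the covariance lay below its highest (0.0627). The covariances were 0.0593, 0.0498 and 0.0443 against 0.0577, 0.0566 and 0.0573 simulated. With the controls split into separate sets the mean r was -0.0850, -0.131 and -0.185 over 10 splits. It ranged from -0.347 to 0.0675, from -0.382 to 0.0113 and from -0.425 to -0.0288. The sets of controls can differ in lane and library profile, which can push r below 0 without an effect of exposure. No values without such an effect were computed for these splits, so no conclusion is drawn from them.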

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

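The tests of the sequencing lane, of tRNA features that move together and both tests of the hairpins were chosen only after the result was seen, as were the splits without a filter on low counts and the splits that balance lane and libraries 5 and 6.

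The values here come from single libraries far from the others of their group, by Dixon's test at the 95% level. Chance sets apart about 1 in 20 groups, and 19 of 273 groups (6.96%) had such a library. In control replicate 2 the tRNA-Cys sum was 9228 RPM (3044 to 3980 in the others) and mmu-mir-1928 stood at 12895 CPM (4459 to 6200). Control replicate 6 had 1679 RPM of tRNA-Lys (2696 to 3398) and 16007 CPM of piR-mmu-398716 (24630 to 30801). Control replicate 5 had tRNA-Tyr-GTA-1-1 at 4.344 CPM (2.098 to 2.669) and tRNA-Tyr-GTA-1-5 at 3.387 CPM (1.42 to 1.957). DBP replicate 4 was deepest of its group with 14.7 M reads (9.835 to 10.99) and had a let-7 sum of 10.61 RPM (6.832 to 7.663). DBP replicate 2 had tRNA-Tyr-GTA-1-5 at 6.855 CPM (3.041 to 3.576).

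DEHP replicate 6 was shallowest of its group with 7.945 M reads (10.52 to 12) and had piR-mmu-398716 at 14102 CPM (22438 to 28888). In DEHP replicate 3 the tRNA-Cys sum was 3280 RPM (5375 to 7090), mmu_circ_0001559 of Zfp536 stood at 0.5837 CPM (1.26 to 1.587) and mmu-mir-1961 at 2873 CPM (5708 to 8277). DEHP replicate 1 had 4505 RPM of tRNA-Lys (2279 to 2915) and 27225 of tRNA-Pro (14533 to 17826). DEHP replicate 5 had piR-mmu-2004057 at 2.076 CPM (4.134 to 5.587). In the mixture, replicate 4 had a tRNA-Asp sum of 3776 RPM (4301 to 4600) and replicate 6 had Gm10646 (ENSMUST00000213227.1) at 89.25 CPM (1.206 to 1.737).

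The first pattern is the calls of tRNA lists higher against controls with the preset correlation. Of 43 called tRNA lists 0 were left when the correlation between tRNA features that move together was estimated (median 0.678), so shared movement of tRNA features may account for these calls. Control library 2 is unlikely to be the whole source, since 36 lists were called over the 3 comparisons without it, against 44 with it. Chance could not be excluded: for DBP 29 of 100 splits of the same libraries called as many lists as the real 17 (highest other 22), for DEHP 33 called as many as 14 (highest 20), and for the mixture 36 called as many as 13 (highest 19). Among 100 splits that balance lane and libraries 5 and 6 as the real groups do, 26 called as many in each comparison (highest 20, 19 and 21), and an effect of exposure stays open.

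The second pattern is the distance of libraries 5 and 6 of every group from libraries 1 to 4, with control replicate 2 (12.6 on the first principal component) as an exception that lay nearer to libraries 5 and 6. Sequencing lane is argued against as the source, since 0 of the 4 libraries numbered 4, on the same lane, lay nearer to libraries 5 and 6 on the first principal component, which is part of how the pattern was seen, and the lane term fell from 923 to 3 calls beside a term for libraries 5 and 6. Depth is argued against too, since the median r between libraries 5 and 6 of different groups was 0.513 after thinning to 7944772 reads, against 0.535 before. A few abundant features do not carry it alone, since r was 0.531 without the 50 most abundant features, which held 63.3% of reads. No biological explanation was tested, since the groups give none, and a batch in collection or library preparation stays open.

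The third pattern is that a few hairpin entries hold most miRNA reads: 10 hairpins held 80.6% of hairpin reads. Processed mature arms are argued against for most of them, since in only 1 of the 10, mmu-mir-2137, did the mature arms hold at least 50% as many reads. How reads were shared between hairpin and mature entries is not given in the sources used here, which limits this argument. Sequence shared with other transcripts may add to the pattern, and 4 of 9 leading hairpins with a GENCODE name shared 20 bases with 5 or more other genes, against 81 of 1135 other hairpins (7.14%, Fisher exact p = 0.00268). For those 4, mmu-mir-1928, mmu-mir-6240, mmu-mir-3470b and mmu-mir-6236, it cannot be told apart from true hairpin reads, because the reads themselves were not analysed here. The hairpins mmu-mir-1961, mmu-mir-2137, mmu-mir-3060 and mmu-mir-5100 shared 20 bases with 0 other genes each. That leaves shorter stretches and sequences outside these genes open, so no conclusion is drawn for them.

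Other splits of the same libraries tested whether chance can be excluded for the counts of features. It could not be at the criterion of the labels: 50 of 100 splits gave as many features as the real 54 for DBP (highest other 519), 69 as many as 29 for DEHP (highest 854) and 75 as many as 31 for the mixture (highest 622). These splits do not balance libraries 5 and 6, as the real groups do. Among 100 of the 120 splits that balance them and lane, 35, 54 and 47 gave as many (highest others 318, 140 and 86), so chance could not be excluded there either. At adjusted p under 0.05 the real count was 0 by edgeR in each comparison (DESeq2 0, voom 0, and 366, 218 and 203 by edgeR at unadjusted p under 0.05 for DBP, DEHP and the mixture), and any split gives at least 0 (100 of 100), so that this says nothing about chance. Of the other splits 4, 3 and 5 gave more than 0 for DBP, DEHP and the mixture against control. The highest others were 171, 639 and 295 for DBP, DEHP and the mixture against control, 0 for DBP against DEHP, 1 and 9 for the mixture against DBP and DEHP, and 2 for the interaction. The splits with the highest counts of filtered features against control put libraries 5 and 6 of both groups on the same side, so they point to a structure of the samples. Without a filter on low counts 4 of 25 splits called as many features as the real 71 for DBP (highest other 441), and chance could not be excluded.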

How the results depend on the processing

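The fits of libraries 1 to 4 alone and of libraries 5 and 6 alone, the extra term for libraries 5 and 6 and the list tests without control replicate 2 were chosen after seeing the data. Of the values recomputed, 799 of named features stayed on their side of the threshold. No class share passed the adjustment under any alternative, which says nothing of stability within a single lane, where no p can pass: the miRNA share differed for DBP by -1.32 percentage points on lane 6 and 0.740 on lane 7. Counts of features stayed within 1.5 times the count first given in 276 cases and did not in 35, and counts of lists in 11 and not in 10. Of the named features 257 values missed the criterion of the labels with the same direction, and 0 turned. For what follows the cause was not tested unless it is given.

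With library totals alone 19 features met the criterion of the labels for DEHP. With no filter (60115 features tested) edgeR called 71 features at adjusted p under 0.05 for DBP, 6 for DEHP, 5 for the mixture, 3 for DBP against DEHP, 17 for the mixture against DBP, 3 for the mixture against DEHP and 20 for the interaction, and 606, 373 and 332 met the criterion for DBP, DEHP and the mixture. The stricter filter tested fewer features (1692), and 8, 1 and 2 met it. Voom with quality weights gave 89, 46 and 59. With only the 2 groups compared it was 15 for DEHP. With fewer libraries, lane 6 alone gave 262 for DBP and 90 for the mixture, lane 7 alone 17 and 20, and libraries 1 to 4 alone 62 for the mixture. Libraries 5 and 6 alone gave 172, 66 and 151 for DBP, DEHP and the mixture, and at adjusted p under 0.05 173 for the mixture against DBP, 1 for the mixture against DEHP and 49 for the interaction. Leaving out each library in turn gave 24 to 165 for DBP (without control replicate 2 and without control replicate 4), 22 to 62 for DEHP (without DEHP replicate 2 and without control replicate 4) and 21 to 58 for the mixture (without mixture replicate 2 and without control replicate 4).

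Lists called numbered 0, 0 and 0 for DBP, DEHP and the mixture with the correlation estimated, 0, 0 and 0 with fry, and 6, 9 and 5 with each class on its own, of which 3, 5 and 3 pointed higher and 3, 4 and 2 lower. Without control replicate 2 it was 6 for the mixture. With each class on its own a list is compared with its own class only, and these called lists then pointed lower, only the sperm 5′ list of the mixture past the threshold. They were for DBP the tRNAs of sperm 5′ fragments (adjusted p = 0.216), tRNA-Gly (0.851), tRNA-iMet (0.431), tRNA-Lys (0.858) and tRNA-Pro (0.359), for DEHP the tRNAs of sperm 5′ fragments (0.120) and tRNA-Arg (0.596), and for the mixture the tRNAs of sperm 5′ fragments (0.00859), tRNA-Arg (0.796), tRNA-Cys (0.667), tRNA-Glu (0.140) and tRNA-Ile (0.667).

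With replicate number as a block in place of lane, edgeR called 0 features at adjusted p under 0.05 (381, 248 and 219 at unadjusted p under 0.05), and 58, 32 and 40 met the criterion. The labels name no animal or donor shared by libraries of the same number. In 12 of 24 libraries the best match in another group had the same number, and r was over 0.1 in 28 of 36 pairs of the same number. Between groups the median r was 0.535 among libraries 5 and 6 and 0.179 among libraries 1 to 4 whatever the number, against 0.289, 0.0306, 0.224 and 0.128 for pairs sharing number 1, 2, 3 or 4. With an extra term for libraries 5 and 6, 73, 36 and 43 met the criterion and edgeR called 0 at adjusted p under 0.05 (446, 293 and 253 at unadjusted p under 0.05). Read number limits what the miRNA lists can show: miR-34 with miR-449 had 124 reads over 24 libraries, and erythrocyte miRNAs 23.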

Other observations

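The otherRNA class, absent from the mapping order, was described after the main comparisons and weighed against no explanation. It held antisense RNA (45.7% ± 6.54 of its reads, SD, n = 24), misc_RNA (23.02% ± 3.57) and snoRNA (3.84% ± 1.25), and the strand of the reads is not given in the sources used here, so that antisense reads are uncertain. Among its abundant entries were 0610038B21Rik (8.79% ± 5.17), the 7SL RNA genes Rn7s2 (7.83% ± 1.28) and Rn7s1 (7.21% ± 1.26), part of the signal recognition particle, and the Y RNA Rny3 (1.996% ± 1.12). After DEHP the snRNA Gm22073 stood at 8.82 ± 6.65 CPM (SD, n = 6) against 2.64 ± 1.50 in controls (log2 1.76 ± 0.43, SE), which did not pass the adjustment (edgeR adjusted p = 0.999). Of 3753 tested features edgeR called 0 at adjusted p under 0.05 in each comparison with control, DESeq2 0 and voom 0. At unadjusted p under 0.05 edgeR called 151, 97 and 93 for DBP, DEHP and the mixture, where chance gives 187.65, and 14, 14 and 12 met the criterion of the labels.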
